A study of Mus musculus with 9 samples.

How the data were processed

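Liver RNA of rats in 3 groups (normal, fibrosis and schisandrin B, with 3 libraries each) was sequenced on the Ion Proton platform. Samples were grouped by the source names in the labels. The deposited file holds raw counts per gene, whole numbers without normalization, for 37203 gene entries and 9 libraries. The aligner, the counting tool and their versions are not given in the sources used here. The labels list the organism as mouse and the build as GRCm38, but give the strain as Wistar rat. The gene symbols are rat symbols, with 1317 names starting RGD, 1687 starting Olr and 54 starting RT1, so genes are reported by the symbols of the file without positions. Library totals ran from 10320299 to 16255167 counts. Levels are TMM-scaled CPM. A floor of 3 counts corresponds to 0.176 to 0.287 CPM per library. Intervals and floors cover counting error only.

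Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr, which left 14581, and libraries were scaled by TMM factors. A quasi-likelihood model with robust dispersions was fitted to all 9 libraries with one mean per group, and each pair of groups was tested with an F test. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called, with no limit on the fold change, and rose and fell are used for called genes. The labels give no batch, and replicate numbers follow the order of the deposit, so no covariate or pairing was used. The labels do not say whether the 3 libraries of a group come from separate animals, so SDs and p-values measure the spread between these libraries. A change is given as log2 fold change with its SE. Where a group had 0 counts the fold is a lower bound, with the group set to 3 counts per library and averaged. With 1 to 3 counts in a group, the ratio of pooled rates is given with an exact 95% counting interval. The check on simulated data planted 200 changes in each comparison. It recovered 78% to 84% of the 4-fold and 16% to 30% of the 2-fold changes, and 5.8% to 13.8% of the calls were false.

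Gene lists for pathways and cell types, and the rule for the genes to be named, were written before the data were examined. The rule takes up to 8 genes with the largest rise and 8 with the largest fall per comparison. These had to be called, to have no overlap between the groups, a mean of at least 5 CPM in the higher group and a proper symbol. It adds up to 4 members of each list with the lowest adjusted p, and Acta2, Col1a1, Col1a2, Col3a1, Timp1, Tgfb1, Nfe2l2, Nqo1, Hmox1 and Smad7 in every comparison. Kdm5d, Eif2s3y and the immediate early genes below rank 4 were chosen after their values had been seen. Lists with at least 5 tested members were tested with limma 3.58.1. Camera with a preset correlation of 0.01 compares a list with all other genes, and camera with an estimated correlation is given beside each call. Camera made 19, 15 and 10 calls in the 3 comparisons, and 0 with the estimated correlation. Fry, which tests whether a list moves one way on balance, made 25, 20 and 9.

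The effects of CCl4 and of schisandrin B were compared across genes by the covariance of the log2 fold changes with a prior count of 2. The reference was 100 simulated data sets without group effects, because both share the fibrosis libraries. Calls were also made in 20 such sets, but sets without group effects cannot serve as a reference for calls. The position on the axis from normal to fibrosis is the slope through the origin of the schisandrin B change on the fibrosis change over genes called in fibrosis against normal. Libraries were projected on axes built without them and compared with exact permutation tests. Principal components used the 500 most variable genes.

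Alternatives were DESeq2 size factors, upper-quartile factors and library totals for scaling; no filter and a mean of at least 5 CPM; DESeq2 1.42.0 and limma voom as tests; fits on only the 2 groups compared; 1 surrogate variable from sva 3.50.0; omission of the 20 most counted genes; stricter thresholds; prior counts of 0.5 and 5; and the omission of each library in turn. Tables and figures were prepared with Python 3.11.15 and matplotlib 3.10.9. Reads in the Cyp2c, Cyp3a, Cyp4a, Mup, Sult2a, Serpina and Hspa1 families can be shared between paralogs, so their single-gene values are uncertain. Rat reference sequence was not used here.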

Results

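RNA was sequenced from rat liver in 9 libraries of 3 groups, with 3 libraries per group. The normal group had received olive oil. The fibrosis group had received carbon tetrachloride (CCl4), a solvent that hepatocytes turn into a toxic radical, at 2 mL/kg of a 50% mixture in olive oil, 3 times a week for 8 weeks. The schisandrin B group had received the same CCl4 course, and from week 4 also schisandrin B, a lignan from Schisandra fruit, daily for 4 weeks. The study used daily doses of 25 and 50 mg/kg, and the sources used here do not say which of them applies to the 3 libraries, or whether the libraries of a group come from separate animals. The number of counts assigned to genes ran from 10320299 to 16255167 per library, and 14581 genes held enough counts to be tested. Albumin transcripts took 13.92% to 17.1% of the counts in normal libraries, 4.18% to 7.65% in fibrosis libraries and 13.09% to 14.33% in schisandrin B libraries.

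The groups were well apart and the libraries of a group were alike. On the 500 most variable genes the first principal component held 61.3% of the variance and separated fibrosis from normal libraries. The second held 29.5% and set the schisandrin B libraries apart from both other groups. The mean correlation across genes, which are not independent replicates, was 0.972 within normal, 0.951 within fibrosis and 0.974 within schisandrin B libraries. Between groups it was 0.823 for normal with fibrosis, 0.845 for fibrosis with schisandrin B and 0.914 for normal with schisandrin B. Fibrosis replicate 1 lay farther from its group than any other library: its chi-square per degree of freedom was 98.02 against fibrosis replicate 2 and 116.46 against replicate 3, where the other pairs of a group ranged from 15.14 to 43.7.

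**Figure D1:**
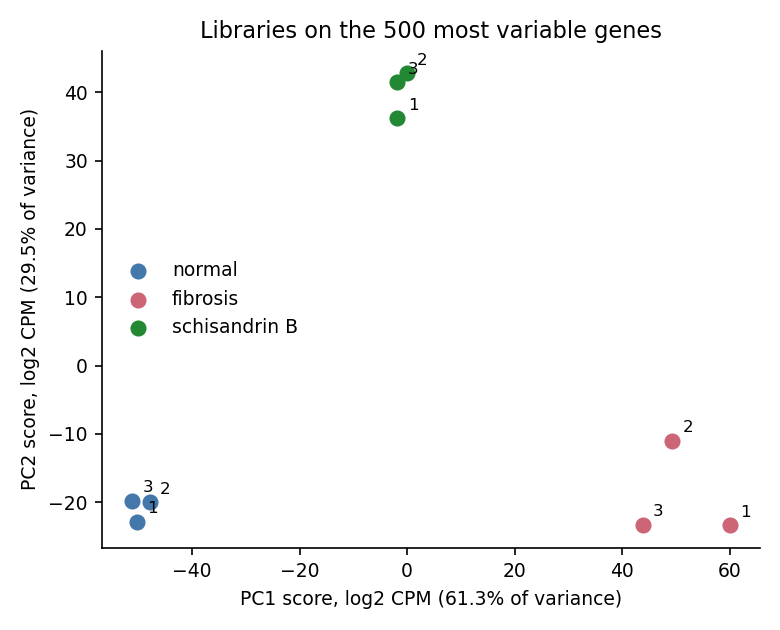
Scores of the 9 libraries on the first principal components of log2 CPM over the 500 most variable genes, one point per library with its replicate number. On the first component normal libraries sit between -51.1 and -47.9, schisandrin B libraries between -1.9 and -0.1 and fibrosis libraries between 43.8 and 60.

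The libraries labelled normal differed from the CCl4 libraries in sex-linked transcripts. Kdm5d and Eif2s3y, both on the Y chromosome, had 0 counts in all 3 normal libraries and 8.04 ± 2.39 and 10.4 ± 1.16 CPM (SD, n = 3) in fibrosis libraries. In schisandrin B libraries they stood at 12.3 ± 1.19 and 11.9 ± 1.46 CPM (SD, n = 3). The labels describe every animal as male. Of the fixed list of sex-biased rat liver genes, 9 of 10 male-biased entries were higher and 6 of 7 female-biased entries were lower in schisandrin B than in normal libraries. A direction against the normal libraries can therefore hold a difference of sex as well as one of treatment, and the comparison of schisandrin B with fibrosis is the one without this difference. These genes were looked at after the values had been seen.

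**Figure D2:**
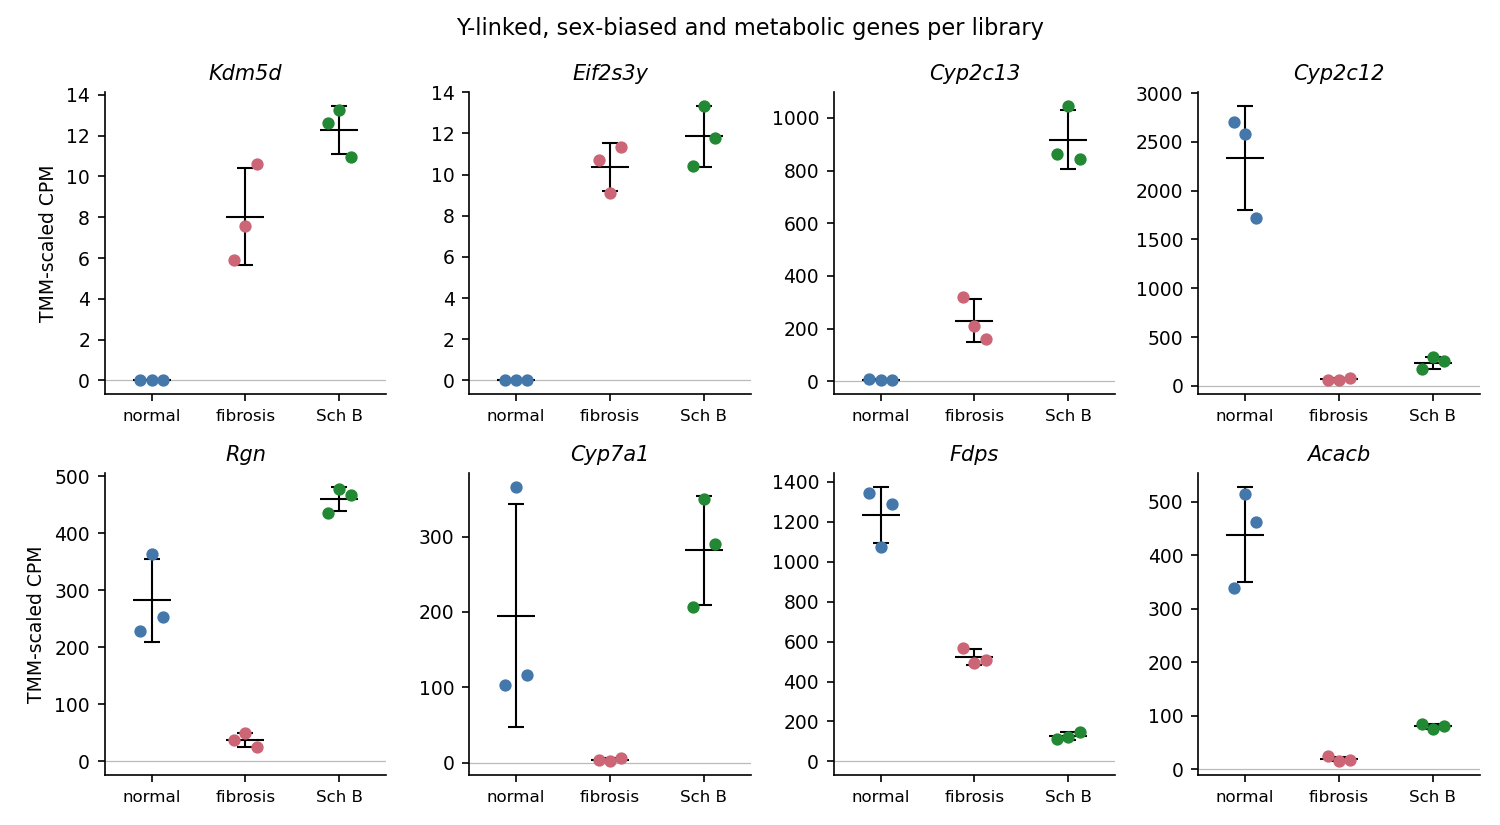
TMM-scaled CPM of 8 genes, one point per library, with the mean and SD of each group of 3. The Y-linked Kdm5d and Eif2s3y are at 0 in normal libraries, Cyp2c12 is highest there, and Fdps and Acacb are lower in both CCl4 groups.

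The first comparison, fibrosis against normal, asks what the CCl4 course changed in the liver. Many genes of the unfolded protein (18 of 24), heat shock (11 of 22), p53 (13 of 18) and Nrf2 (18 of 33) lists rose in the fibrosis libraries. In the same order 0, 0, 1 and 5 fell, and camera with an estimated correlation called none of these lists. Genes of hepatocyte metabolism fell, among them those of the pericentral zone, where CCl4 is activated, with a list median of -2.17 on the log2 scale. Smooth muscle actin and matrix proteases rose, while Col1a1, Col1a2 and Col3a1, the main fibrillar collagens of scar tissue, showed no called change. edgeR called 7041 of 14581 genes (48.3%), 3708 higher and 3333 lower, and 4894 of them changed at least 2-fold. The groups did not overlap in 8132 genes (55.8%), where chance gives 10%. Scaling by library totals alone moved the median gene by 0.43 on the log2 scale and the share called higher from 52.7% to 74.7%. Upper-quartile scaling shifted the median by -0.11.

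Stress genes made up the clearest rise against the libraries labelled normal. Of 24 genes of the unfolded protein and integrated stress response 18 rose and 0 fell, over all genes and adjusted over the list alone. Ddit3, a transcription factor that promotes cell death, rose from 12.5 ± 2.46 to 195 ± 17.7 CPM (SD, n = 3), and Trib3, its target, rose by 5.32 ± 0.37 (SE) on the log2 scale with an edgeR adjusted p of 2.49e-06. Of 18 p53 targets 13 rose and 1 fell (14 and 2 adjusted over the list alone), among them the cell cycle inhibitor Cdkn1a at 6.12 ± 0.41 and the death receptor Tnfrsf10b at 4.30 ± 0.30 on the log2 scale. Of 22 heat shock and early response genes 11 rose and 0 fell, the same adjusted over the list alone, with the small chaperone Hspb1 at 6.53 ± 0.45. Hspa1a rose as well, but its reads can be shared with the paralog Hspa1b and its level ranged widely, 376 ± 446 CPM (SD, n = 3). The limma camera test called these lists up, with an adjusted p of 1.21e-07 for the unfolded protein list (adjusted p = 0.147 with an estimated correlation), 3.41e-05 for p53 (0.263) and 0.00497 for heat shock (0.603).

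Antioxidant genes moved with them. Of 33 Nrf2 targets 18 rose and 5 fell (19 and 5 adjusted over the list alone), and camera gave an adjusted p of 0.00194 (adjusted p = 0.429 with an estimated correlation). Srxn1, which repairs oxidised peroxiredoxins, rose from 15.7 to 1299 CPM, and the glutathione transferase Gstm3 rose by 5.68 on the log2 scale. The cystine transporter Slc7a11 had 0 counts in normal libraries and was at least 129-fold higher in fibrosis libraries. Hmox1 rose by 3.30 ± 0.79 (edgeR adjusted p 0.00748), although its level varied between fibrosis libraries, 627 ± 783 CPM (SD, n = 3). Nqo1 was 1.20 ± 0.49 higher without a call (edgeR adjusted p 0.0669), and it was called in 5 of 14 alternatives, where its adjusted p ranged from 0.0183 to 0.285. Nfe2l2, which encodes Nrf2 itself, had an edgeR adjusted p of 0.741, and over the alternatives it was called only with library totals (0.0222) and its adjusted p ranged up to 0.925.

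Matrix genes gave a mixed picture. Acta2, the smooth muscle actin of activated stellate cells, rose by 1.54 ± 0.32 (edgeR adjusted p 0.00196), and the protease inhibitor Timp1 rose by 1.63 ± 0.32 (0.00147). Of 14 matrix proteases and inhibitors 9 rose and 1 fell, the same adjusted over the list alone (camera adjusted p 0.0406, and adjusted p = 0.546 with an estimated correlation), and camera lost the call with library totals (0.0638) and without fibrosis replicate 1 (0.107). Mmp3, which cleaves laminin and proteoglycans, had 1 count in normal and 1659 in fibrosis libraries, a ratio of 1510 with a 95% counting interval of 271 to 59700. Of 16 collagens 4 rose and 1 fell, the same adjusted over the list alone, and with library totals 9 rose and 1 fell. Camera did not call them (adjusted p 0.25) except without fibrosis replicate 2 (0.0412). Col5a2 rose by 1.03 and Col18a1 fell by 0.93 on the log2 scale. Col1a1, Col1a2 and Col3a1 differed by 0.38 ± 0.44, 0.17 ± 0.39 and 0.13 ± 0.27 without a call, with edgeR adjusted p of 0.506, 0.739 and 0.718. Of 24 other matrix genes 8 rose and 2 fell, the same adjusted over the list alone, with the laminin chain Lamc1 up 2.88 and decorin, Dcn, up 2.11 on the log2 scale.

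The TGF-beta and Smad list had no common direction, with 7 of 29 genes higher and 6 lower (7 and 5 adjusted over the list alone). Its mean was 0.03 and its median -0.16 on the log2 scale, and camera pointed down with an adjusted p of 0.71. With library totals 9 were higher and 2 lower, with a median of 0.24. The inhibitory Smad7 fell by 1.34 ± 0.22 (edgeR adjusted p 0.000473). Tgfb1 was not called (edgeR adjusted p 0.545) except without fibrosis replicate 1, where it was 0.62 lower on the log2 scale with an adjusted p of 0.0306, and over 14 alternatives its adjusted p ranged up to 0.967. Among 22 stellate cell and fibroblast markers 9 rose and 3 fell, the same adjusted over the list alone. Cygb rose by 1.58, while Lrat, which stores retinol in resting stellate cells, fell by 3.45 on the log2 scale, so the markers of this cell type did not move as a block.

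Hepatocyte genes fell across pathways, and 12 of 18 general hepatocyte markers fell too (10 fell and 2 rose with library totals). No list was adjusted for these markers, so a pathway was not told apart from the cell type. Of 16 pericentral genes 14 fell and 0 rose, the same adjusted over the list alone (camera adjusted p 1.21e-07, and adjusted p = 0.203 with an estimated correlation). Cyp2e1, the enzyme that activates CCl4, fell by 2.99 ± 0.32, Oat fell by 4.26 ± 0.38 and Rgn fell by 2.90 ± 0.28 on the log2 scale. Of 17 periportal genes 12 fell and 0 rose, the same adjusted over the list alone (camera adjusted p 0.000132, and adjusted p = 0.445 with an estimated correlation). Bile acid genes fell in 17 of 23 with 1 rise (18 and 1 adjusted over the list alone), led by the transporter Slco1b2 at -3.92, and the cholic acid enzyme Cyp8b1 at -3.55. Urea cycle and amino acid genes fell in 20 of 30 with 2 rises, the same adjusted over the list alone (13 and 4 with library totals), among them Cth and Glul at -3.55 and -2.15. Fatty acid oxidation genes fell in 19 of 30 with 2 rises (20 and 2 adjusted over the list alone), with Fabp1 at -3.59 and Ehhadh at -3.82. The camera adjusted p of these 3 lists were 1.38e-06, 7.55e-06 and 6.98e-06, and with an estimated correlation 0.263, 0.429 and 0.461.

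Lipid synthesis genes fell as well. Of 24 cholesterol genes 18 fell and 1 rose (19 and 1 adjusted over the list alone; camera adjusted p 1.21e-07, and adjusted p = 0.429 with an estimated correlation). Hmgcs1, which feeds the sterol pathway, fell by 3.68 ± 0.36 and Nsdhl fell by 2.75 ± 0.25. Of 20 fatty acid synthesis genes 11 fell and 3 rose, the same adjusted over the list alone (camera adjusted p 0.00256, and adjusted p = 0.429 with an estimated correlation), with Acacb at -4.53 and the desaturase Fads2 at -4.71 on the log2 scale. Of 26 interferon response genes 14 fell and 0 rose, the same adjusted over the list alone (camera adjusted p 1.21e-05, and adjusted p = 0.533 with an estimated correlation). The immunoproteasome subunit Psmb9 fell by 2.46 on the log2 scale, and 10 of 12 T and NK cell markers fell as well, but only 2 of them with library totals.

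Many of the largest changes against the libraries labelled normal were in genes that differ between male and female rat liver or belong to families with shared reads. Sdcbp2, Cpa1, Ky and Mmd2 are neither on the fixed sex-biased list nor in the families named for shared reads. With 0 counts in normal libraries, the organic anion transporter Slc22a8 was at least 360-fold higher, the sulfotransferase ste2 at least 233-fold, Mup4 at least 99.5-fold, Cyp3a85-ps at least 87.1-fold and the steroid enzyme Hsd3b5 at least 80.8-fold. Mup5 rose by 11.01 ± 0.94 on the log2 scale. Sdcbp2, with 1 count in normal and 3200 in fibrosis libraries, had a ratio of 2910 and a counting interval of 522 to 115000. In the other direction A1bg fell from 5903 to 1.17 CPM, Akr1b7 from 470 to 0.189 and Sult2a2 from 302 to 0.188. With 0 counts in fibrosis libraries, Cpa1 was at least 624-fold and Ky at least 69.9-fold lower. Mmd2 had 1 count left in fibrosis libraries, a ratio of 609 (interval 109 to 24100). Cytochrome P450 genes split, with 11 of 45 higher and 25 lower (12 and 27 adjusted over the list alone). The male-specific Cyp2c13 rose by 5.31 and the female-specific Cyp2c12 fell by 5.11, both uncertain because the Cyp2c paralogs share reads, and camera called the list down (adjusted p 0.00219, and adjusted p = 0.429 with an estimated correlation).

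The second comparison, schisandrin B against fibrosis, asks what the compound changed on top of CCl4, and Y-linked transcripts were present in all 6 libraries. The stress genes that were high in fibrosis libraries were low with schisandrin B. Hepatocyte genes were higher, with all pericentral genes called. Col1a1, Col1a2 and Col3a1 did not fall with the stress genes, and were called higher with schisandrin B than in fibrosis libraries, calls that scaling by library totals ended. edgeR called 6895 genes (47.3%), 3284 higher and 3611 lower, and 4790 of them changed at least 2-fold. The groups did not overlap in 8285 genes (56.8%), where chance gives 10%. Library totals moved the median gene by -0.27 and the share called higher from 47.6% to 32.6%, and upper-quartile scaling moved the median by 0.13 on the log2 scale.

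**Figure D3:**
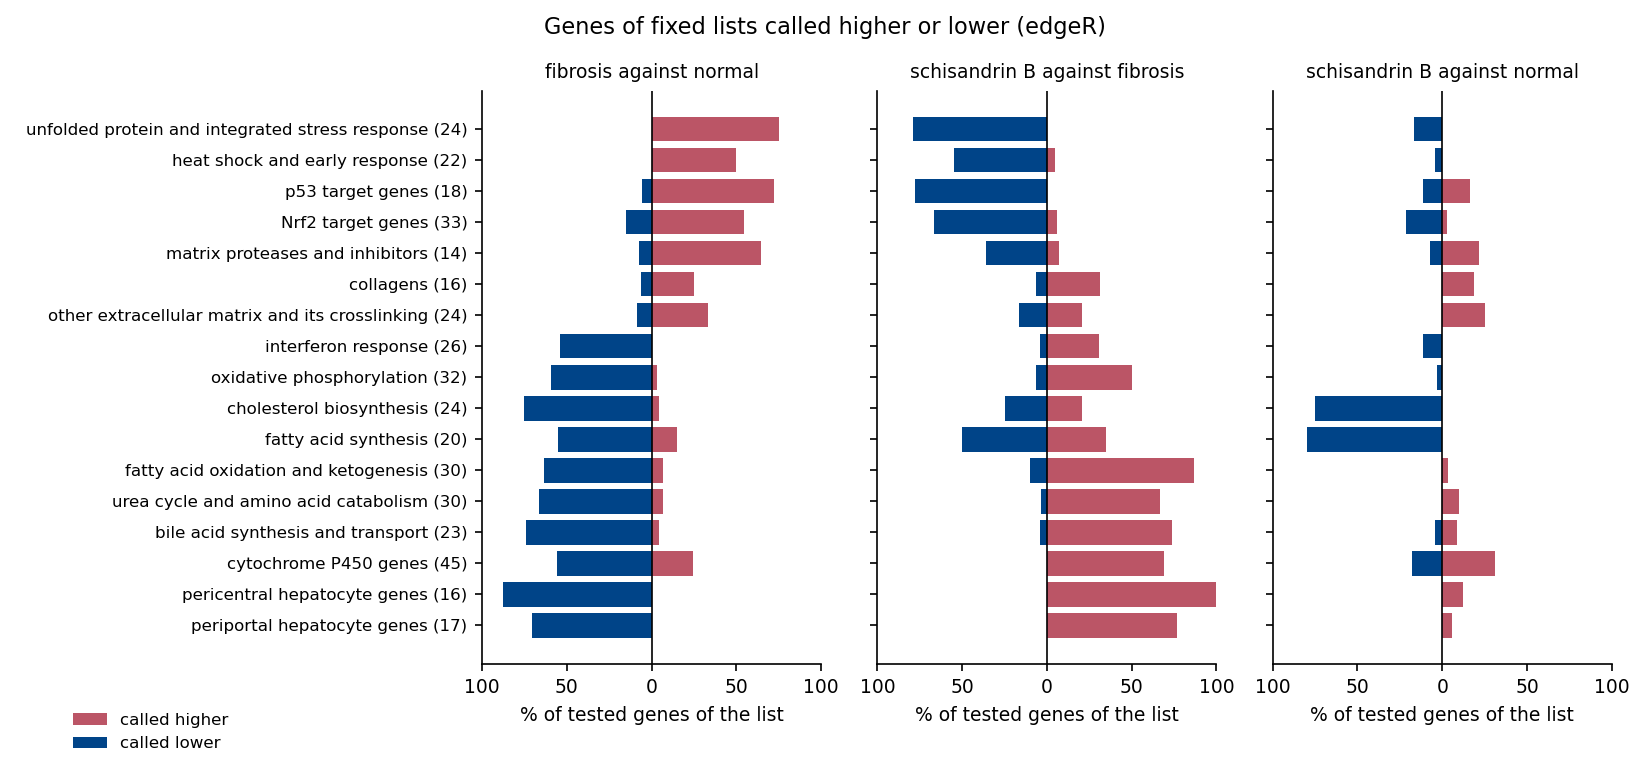
Percent of the tested genes of 17 fixed lists that edgeR called higher (right) or lower (left) in each comparison, with the number of tested genes in brackets. Stress lists rise and metabolic lists fall in fibrosis against normal and go the other way in schisandrin B against fibrosis, apart from cholesterol and fatty acid synthesis, which go both ways there. With library totals the collagens of the middle panel become 2 higher and 2 lower and the other matrix genes 4 higher and 7 lower.

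Of 24 unfolded protein and integrated stress response genes 19 fell and 0 rose (20 and 0 adjusted over the list alone). Ddit3 fell from 195 to 14.7 ± 0.708 CPM (SD, n = 3) and Trib3 fell by 5.21 ± 0.36 (SE). Of 18 p53 targets 14 fell and 0 rose (15 and 1 adjusted over the list alone), with Cdkn1a at -3.72 and the kinase Plk2 at -3.01 on the log2 scale. Of 22 heat shock and early response genes 12 fell and 1 rose, the same adjusted over the list alone, with Hspb1 at -5.81 and Myc, a growth regulator at -3.80. Camera called the 3 lists down with adjusted p of 1.57e-09, 1.49e-05 and 0.000126. With an estimated correlation the values were 0.0753, 0.185 and 0.615. Fibrosis replicate 1 was the highest library for Ddit3, Hspb1 and Cdkn1a, and without it each of these genes was still called.

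**Figure D4:**
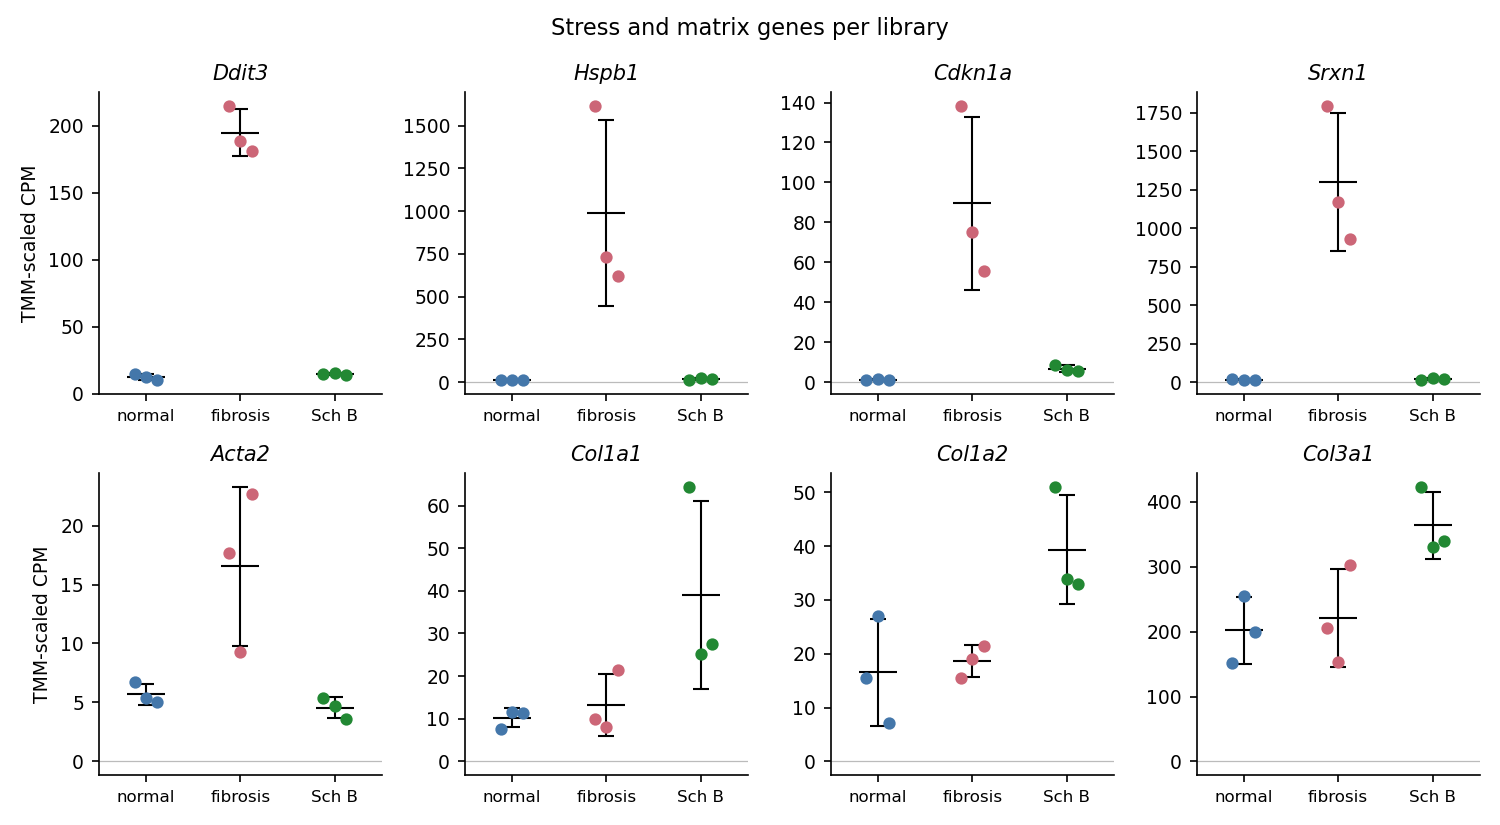
TMM-scaled CPM of 4 stress genes and 4 matrix genes, one point per library, with the mean and SD of each group of 3. Ddit3, Hspb1, Cdkn1a, Srxn1 and Acta2 peak in fibrosis libraries, and Col1a1, Col1a2 and Col3a1 are highest in schisandrin B libraries.

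Of 33 Nrf2 targets 22 fell and 2 rose (22 and 3 adjusted over the list alone; camera adjusted p 1.39e-05, and adjusted p = 0.185 with an estimated correlation). Srxn1 fell by 6.04 ± 0.41, Nqo1 fell by 2.78 ± 0.52 and Hmox1 fell by 3.94 ± 0.82, with edgeR adjusted p of 4.58e-06, 0.00176 and 0.00352. Slc7a11 had 0 counts with schisandrin B and was at least 117-fold lower. Nfe2l2 was again not called (edgeR adjusted p 0.581). Fosl1, an AP-1 subunit, was at least 345-fold lower, Sdcbp2 at least 297-fold and the stromelysin Mmp10 at least 69.4-fold, each with 0 counts in schisandrin B libraries. Zfand2a, an arsenite-inducible proteasome adapter, fell from 2959 to 15.2 CPM, Hspa1a fell by 8.33 ± 1.30 and Agpat9, a glycerolipid enzyme, fell by 7.63 ± 0.67. Mmp3 kept 2 counts, a ratio of 684 with a counting interval of 189 to 5650.

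Genes of hepatocyte function were higher with schisandrin B. All 16 pericentral genes rose, and so they did adjusted over the list alone (camera adjusted p 5.14e-09, and adjusted p = 0.14 with an estimated correlation). Rgn, a calcium-binding protein, rose from 37.8 to 460 ± 21.6 CPM (SD, n = 3), Glul rose by 2.30 and Cyp2e1 by 2.39 on the log2 scale. Of 17 periportal genes 13 rose and 0 fell, the same adjusted over the list alone (camera adjusted p 0.000133, and adjusted p = 0.431 with an estimated correlation). Fatty acid oxidation genes rose in 26 of 30 and fell in 3 (27 and 3 adjusted over the list alone), with Ehhadh up 3.98 and the ketone enzyme Bdh1 up 4.29. Urea cycle and amino acid genes rose in 20 of 30 and fell in 1, the same adjusted over the list alone, with Nags up 2.24 and Kmo up 2.89. Camera gave these lists adjusted p of 2.30e-08 and 3.91e-07, and with an estimated correlation 0.367 and 0.328. General hepatocyte markers rose in 10 of 18 with 0 falls (11 and 2 adjusted over the list alone, 8 and 3 with library totals) and a median of 0.84, below the pericentral median of 2.46. Gluconeogenesis and glycogen genes rose in 6 of 11 and fell in 2, the same adjusted over the list alone, without a camera call (adjusted p 0.0718).

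Bile acid genes rose in 17 of 23 and fell in 1 (18 and 1 adjusted over the list alone; camera adjusted p 1.40e-07, and adjusted p = 0.144 with an estimated correlation). Cyp7a1, the first enzyme of bile acid synthesis, rose from 3.92 to 282 CPM, and Nr0b2, the repressor that bile acids induce, rose by 6.22 ± 1.04. The uptake transporters Slco1b2 and Slco1a1 rose by 4.31 and 2.42, and Cyp8b1 rose by 2.61 on the log2 scale. Cytochrome P450 genes rose in 31 of 45 with 0 falls (31 and 1 adjusted over the list alone; camera adjusted p 1.14e-08, and adjusted p = 0.144 with an estimated correlation). Of 23 genes induced through the xenobiotic receptors PXR and CAR 14 rose and 4 fell, the same adjusted over the list alone (camera adjusted p 0.00478, and adjusted p = 0.289 with an estimated correlation). Sult2a1 and Cyp2c7 rose by 4.11 and 2.28, both in families with shared reads, while the efflux pump Abcb1a fell by 2.69. The median of this list was 1.48 on the log2 scale, between those of the general hepatocyte markers and of the pericentral genes. Other large rises were those of Nrep at 6.32, the acyl-CoA synthetase Acsm5 at 6.09, Adam11 at 5.59, the aldehyde oxidase Aox3 at 5.38, Fam179a at 5.29 and the epoxide hydrolase Ephx2 at 5.27 on the log2 scale.

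Lipid synthesis genes went both ways. Of 24 cholesterol genes 5 rose and 6 fell (4 and 6 adjusted over the list alone), and with library totals 4 rose and 8 fell. Fdps and Sqle changed by -2.03 and -1.93, while Ebp rose by 1.01 on the log2 scale. Of 20 fatty acid synthesis genes 7 rose and 10 fell, the same adjusted over the list alone. The desaturase Fads2 rose by 3.36 and fatty acid synthase, Fasn, fell by 3.42. Neither list was called by camera (adjusted p 0.943 and 0.743).

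Matrix genes did not fall as a group. Of 16 collagens 5 rose and 1 fell (3 and 1 adjusted over the list alone), but with library totals 2 rose and 2 fell, and camera did not call them (adjusted p 0.516). Col1a1 rose from 13.2 ± 7.21 to 39.1 ± 22 CPM (SD, n = 3), Col18a1 and Col5a1 rose by 1.06 and 0.90, and Col12a1 fell by 1.74 on the log2 scale. The log2 rise was 1.55 ± 0.44 for Col1a1, 1.07 ± 0.39 for Col1a2 and 0.72 ± 0.27 for Col3a1, with edgeR adjusted p of 0.0150, 0.0411 and 0.0462. These calls were close to the limit. Over 14 alternatives the adjusted p of Col1a1 ranged from 0.00102 to 0.0835, that of Col1a2 from 0.00646 to 0.152 and that of Col3a1 from 0.00885 to 0.278, while the direction stayed the same. Col1a1 lost its call with library totals and without fibrosis replicate 1 or 2. Col1a2 and Col3a1 each lost theirs in 8 of the 14, among them library totals (0.79 and 0.42 on the log2 scale, adjusted p 0.151 and 0.278) and the omission of any schisandrin B library and of fibrosis replicate 1 or 2. Normal replicate 1 and fibrosis replicate 3 also ended the call of Col1a2 when left out, and normal replicate 3 and a fit of only the 2 groups that of Col3a1.

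Genes of stellate cells went different ways. Acta2 fell by 1.86 ± 0.32 (edgeR adjusted p 0.000718) and Cygb fell by 1.56, and the resting-cell gene Lrat rose by 3.87 on the log2 scale. Stellate cell and fibroblast markers split evenly, 6 higher and 6 lower of 22 (7 and 8 adjusted over the list alone), and with library totals 3 rose and 9 fell. Their median was -0.42 and their mean 0.09 on the log2 scale, and camera pointed down without a call (adjusted p 0.68). Of 24 other matrix genes 5 rose and 4 fell (4 and 4 adjusted over the list alone), and with library totals 4 rose and 7 fell. Sparc rose by 1.08 and Lamc1 fell by 2.82. Of 14 matrix proteases and inhibitors 1 rose and 5 fell, the same adjusted over the list alone, with Timp3 at -1.59. Timp1 was 0.77 ± 0.31 lower without a call (edgeR adjusted p 0.0591), and over 14 alternatives its adjusted p ranged from 0.0180 to 0.221, with a call under library totals and without fibrosis replicate 2. In the TGF-beta and Smad list 5 of 29 rose and 8 fell, the same adjusted over the list alone, and with library totals 2 rose and 12 fell. Smad7 rose by 0.88 ± 0.22 (edgeR adjusted p 0.00650). Tgfb1 was not called (0.0671), except with library totals and without fibrosis replicate 2, and over 14 alternatives its adjusted p ranged from 0.0162 to 0.287.

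Of the cholangiocyte and ductular markers 6 of 14 fell and 1 rose, the same adjusted over the list alone, and camera gave an adjusted p of 0.0602. Krt18 and Krt8, keratins that stressed hepatocytes also make, changed by -3.12 and -1.97. Of 6 neutrophil markers 5 fell and 1 rose, the same adjusted over the list alone (camera adjusted p 0.0577). Csf3r fell by 2.67, Cxcr2 fell by 3.35 and S100a9 fell by 2.46 on the log2 scale. Of 26 interferon response genes 8 rose and 1 fell (8 and 0 adjusted over the list alone; camera adjusted p 0.0812), with Stat2 up 1.57 and Ifi27 up 2.07. The sex-biased list rose in 11 of 17 with 1 fall, the same adjusted over the list alone (camera adjusted p 2.57e-06, and adjusted p = 0.188 with an estimated correlation). Its rises covered 7 of 10 male-biased and 4 of 7 female-biased entries, with Hsd17b2 and Rup2 up 3.74 and 3.50.

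The third comparison, schisandrin B against normal, asks what differed from the olive oil group, and it carries the difference in Y-linked transcripts. Cholesterol and fatty acid synthesis genes were lower, and some collagens and matrix genes were higher. edgeR called 1531 genes (10.5%), 766 higher and 765 lower, and 1014 of them changed at least 2-fold. Of the 1531, 852 (55.6%) were called the same way in fibrosis against normal, which shares the normal libraries. The others are not differences seen to stay from the fibrosis libraries. The count of 1531 depended on single libraries and on the fit. Leaving out 1 library gave 702 to 2814, the highest without fibrosis replicate 1, which is not in this comparison. A fit of only the 2 groups compared gave 2951. The groups did not overlap in 5637 genes (38.7%), where chance gives 10%. Library totals moved the median by 0.16 on the log2 scale and the share called higher from 50% to 70.3%.

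Of 24 cholesterol genes 18 fell and 0 rose (21 and 0 adjusted over the list alone; camera adjusted p 5.93e-21, and adjusted p = 0.201 with an estimated correlation). Fdps fell from 1235 ± 141 to 128 ± 19.3 CPM (SD, n = 3), Mvd fell by 2.26 and Lss fell by 1.98 on the log2 scale. Of 20 fatty acid synthesis genes 16 fell and 0 rose, the same adjusted over the list alone (camera adjusted p 2.07e-12, and adjusted p = 0.201 with an estimated correlation). Acss2, Acacb and Acly, which supply and carboxylate acetyl-CoA, changed by -2.65, -2.46 and -2.87.

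Some matrix genes were higher than in the libraries labelled normal. Of 16 collagens 3 rose and 0 fell (8 and 0 adjusted over the list alone, 5 and 0 with library totals; camera adjusted p 0.00249, and adjusted p = 0.728 with an estimated correlation). Col1a1 rose by 1.93 ± 0.45 (edgeR adjusted p 0.0236), Col5a2 by 1.09 and Col6a2 by 0.86. Each of these calls ended in some alternatives, 4 of 14 for Col1a1, 4 for Col5a2 and 7 for Col6a2, and the highest adjusted p were 0.0846, 0.0836 and 0.164. The omissions that ended the call of Col1a1 were those of each normal library and of schisandrin B replicate 1. For Col5a2 they were normal replicates 1 and 3 and schisandrin B replicates 1 and 3, and for Col6a2 any library of either group, beside limma voom. Col1a2 and Col3a1 were 1.24 ± 0.39 and 0.85 ± 0.27 higher without a call (edgeR adjusted p 0.0680 and 0.0686). Col1a2 was called with DESeq2 (0.0176), with limma voom (0.0456) and without normal replicate 2. Col3a1 was called with DESeq2 (0.0287), with only the 2 groups compared (0.0109) and without any one of the fibrosis libraries, and their adjusted p ranged from 0.0162 to 0.195 and from 0.0109 to 0.214. Of 24 other matrix genes 6 rose and 0 fell (8 and 1 adjusted over the list alone) without a camera call (adjusted p 0.0609), led by the crosslinking enzyme Lox, up 3.19, and the protease Mmp2 rose by 1.69. Sparc rose by 0.81, a call that the omission of any library of the compared groups except schisandrin B replicate 2 ended (adjusted p up to 0.0917).

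Acta2, Timp1, Tgfb1, Nfe2l2, Nqo1, Hmox1 and Smad7 were not called against normal, with edgeR adjusted p of 0.587, 0.113, 0.0662, 0.895, 0.0777, 0.634 and 0.206. On the log2 scale Timp1 was up 0.86 ± 0.32, and the other 6, in the same order, changed by -0.32 ± 0.33, -0.91 ± 0.29, -0.05 ± 0.18, -1.59 ± 0.51, -0.65 ± 0.74 and -0.45 ± 0.22 (SE). A missing call does not show the normal level. Without fibrosis replicate 1 Timp1, Tgfb1 and Hmox1 were called (0.0380, 0.00746 and 0.0133), and without fibrosis replicate 2 Tgfb1 and Nqo1 were (0.0373 and 0.0434). Nqo1 was also called without schisandrin B replicate 1 (0.0382) and with DESeq2 (0.0106), and Tgfb1 with DESeq2 (0.0421). A fit of only the 2 groups compared called Timp1, Tgfb1 and Hmox1 (0.0378, 0.00680 and 0.0144). The highest adjusted p over the alternatives were 0.315, 0.207, 0.776 and 0.224 for Timp1, Tgfb1, Hmox1 and Nqo1. Of the stress lists, p53 targets had 3 of 18 higher and 2 lower, the same adjusted over the list alone (5 and 1 with library totals), with Cdkn1a up 2.40 and Tnfrsf10b up 1.90. Unfolded protein genes had 0 of 24 higher and 4 lower, the same adjusted over the list alone, with the chaperones Pdia3 and Calr at -1.07 and -1.03. With library totals 1 of that list was higher and 2 were lower. Nrf2 targets had 1 of 33 higher and 7 lower (1 and 9 adjusted over the list alone), with Gstm3 up 2.77. Pericentral genes had 2 of 16 higher and 0 lower, the same adjusted over the list alone, namely Nr1i3 and Rhbg, up 3.32 and 2.20. Interferon response genes had 3 of 26 lower and 0 higher, the same adjusted over the list alone, with Psmb8 at -1.65 (camera adjusted p 1.84e-06, and adjusted p = 0.728 with an estimated correlation).

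Many of the largest changes were again those of sex-biased and shared-read families, though Krt23, Cpa1 and Ky belong to neither the fixed sex-biased list nor the named families. With 0 counts in normal libraries ste2 was at least 4480-fold higher, Slc22a8 at least 1200-fold, Cyp3a85-ps at least 424-fold, Hsd3b5 at least 274-fold, Mup4 at least 261-fold and Obp3 at least 144-fold. Mup5 and Cyp3a2 rose by 11.73 ± 0.96 and 10.43 ± 0.58. A1bg fell from 5903 to 0.191 CPM, Sult2a2 fell by 7.50 and the keratin Krt23 fell by 5.96 on the log2 scale, and limma voom did not call Krt23 (adjusted p 0.102, the highest over 14 alternatives, and the lowest was 6.68e-05). Cpa1 had 0 counts with schisandrin B and was at least 517-fold lower. The ratios of Akr1b7 and Ky, with 2 and 1 counts left, were 8060 (counting interval 2230 to 66600) and 506 (90.4 to 20000).

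Most of the changes called in fibrosis against normal ran the other way in schisandrin B against fibrosis. Of the 7041 genes called in fibrosis against normal, 5118 (72.7%) were called in the opposite direction in schisandrin B against fibrosis. Of these 2796 were higher and then lower, where independent lists would share 918, and 2322 were lower and then higher, where they would share 751. Only 50 genes rose and 29 fell in both steps. In 20 simulated data sets without group effects 0 genes were called either way. Without group effects hardly any gene is called at all, so these sets give no reference for the overlap. Both comparisons use the same fibrosis libraries, so part of the excess can come from them. A split chosen after the data were seen put 1 fibrosis library in one comparison and the other 2 in the other. It leaves 1 comparison with a single fibrosis library, so only its covariance is given below. The covariance of the log2 changes across genes was -1.312, where 100 simulated data sets without group effects gave -0.070 (-0.076 to -0.065), and the correlation was -0.762 against a simulated -0.493. With the fibrosis libraries split in this way the covariance was -1.267 to -1.145. On the axis from normal to fibrosis, the position of the schisandrin B group was 0.309. This axis holds the sex-linked difference of the normal libraries as well as CCl4. The position therefore does not measure a return from CCl4 alone. Single libraries projected at 0.039 ± 0.026 for normal, 0.309 ± 0.016 for schisandrin B and 0.934 ± 0.105 for fibrosis (SD, n = 3). The exact two-sided permutation p was 0.1 for schisandrin B against either group, the smallest that 3 against 3 libraries allow.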

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

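The counts of genes shared or not shared with another comparison (5118, 6189 and 679), the fit of only the 2 CCl4 groups without fibrosis replicate 1 (7098), and the split of the fibrosis libraries between the 2 effects were chosen after the data were seen. Counts for fibrosis against normal and schisandrin B against fibrosis stayed within 1.5 times of 7041 and 6895 in every alternative run, with 6045 to 7253 and 5669 to 7022 when single libraries were left out, and no shared call changed sign. The count for schisandrin B against normal, 1531, was less stable. It was 2951 with only the 2 groups compared, 2785 with 1 surrogate variable, 1014 with a 2-fold limit, 547 at an adjusted p under 0.01 and 679 without genes called the same way in fibrosis against normal, a comparison that shares the normal libraries. Leaving out 1 library gave 702 to 2814: 2814 without fibrosis replicate 1, the library farthest from its group, and 931, 1004 and 773 without normal replicates 1, 2 and 3, and 874, 777 and 702 without schisandrin B replicates 1, 2 and 3. The cause was not tested. The covariance of -1.312 became -1.403 with a mean CPM of at least 5, -0.874 without a filter, -1.501 and -1.15 with prior counts of 0.5 and 5, and -1.438 to -1.186 with 1 library left out (-1.186, -1.434 and -1.438 without fibrosis replicates 1, 2 and 3). With separate fibrosis libraries for the 2 effects, 1 and 2 in each of 6 ways, it was -1.267 to -1.145 (-1.26 and -1.267 with fibrosis replicate 1 alone, -1.154 and -1.214 with replicate 2 alone, -1.212 and -1.145 with replicate 3 alone). The position of 0.309 became 0.332 and 0.293 with those prior counts and 0.28 to 0.327 with 1 library left out (0.326 and 0.28 without fibrosis replicates 1 and 2, 0.327 without normal replicate 2). Camera with an estimated correlation called 0 lists in each comparison, where fry called 25, 20 and 9. Single omissions ended the camera call of the matrix proteases against normal (fibrosis replicate 1), of ribosomal proteins in schisandrin B against fibrosis (fibrosis replicate 1, schisandrin B replicates 1 and 2) and against normal (normal replicates 2 and 3, schisandrin B replicate 3), of acute phase proteins (normal replicates 1 and 3) and of fatty acid oxidation (normal replicate 2, schisandrin B replicate 2). Library totals ended the call of the matrix proteases (0.0638). DESeq2 size factors, not planned for the set tests, ended that of ribosomal proteins in schisandrin B against fibrosis (0.0514). Alternatives also added camera calls. In fibrosis against normal these were cell cycle (7 alternatives), collagens, Kupffer cell and sinusoidal markers (1 each). In schisandrin B against fibrosis they were interferon response (4), cholangiocyte and neutrophil markers (3 each), and acute phase, gluconeogenesis and matrix proteases (1 each). In schisandrin B against normal they were Kupffer cell markers (6), other matrix genes (5), sinusoidal (4) and neutrophil markers (2), and Nrf2, PXR and CAR, mesothelium and unfolded protein lists (1 each). Of 2755 values of named genes under the alternatives 2679 kept their call or the lack of one, 44 lost the call and 32 gained one. A called value reversed in 0 cases. Values without a call could change sign and still count as kept. In fibrosis against normal Tgfb1 ranged from -0.62 to 0.18 and Nfe2l2 from -0.05 to 0.49 on the log2 scale. Depth limits the genes near the floor of 3 counts. No paired analysis was possible because the replicate numbers only follow the order of the deposit.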

Other observations

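The tests on Y-linked transcripts, on the share of hepatocytes, on all 14 early response genes, on Col1a1 alone, on exchanged labels and on the sterol pathway were chosen only after the result was seen. Circadian clock genes went both ways, and camera called the list in no comparison (adjusted p 0.286, 0.493 and 0.881), while fry did in fibrosis against normal and in schisandrin B against fibrosis (adjusted p 0.0233 and 0.0145). In fibrosis against normal 5 of 16 rose and 9 fell, the same adjusted over the list alone, and with library totals 6 rose and 5 fell. Arntl rose by 3.58 ± 0.37, while Tef and Dbp changed by -2.14 and -3.68 on the log2 scale. In schisandrin B against fibrosis 7 rose and 4 fell (8 and 5 adjusted over the list alone; 4 and 6 with library totals), with Arntl at -2.88 and Tef and Per2 up 2.77 and 2.86. In schisandrin B against normal 1 of 16 rose and 1 fell (2 and 2 adjusted over the list alone, 2 and 1 with library totals), with Per2 up 1.79. The hour at which the livers were taken is not given in the sources used here. Oxidative phosphorylation genes fell in 19 of 32 in fibrosis against normal with 1 rise (20 and 1 adjusted over the list alone; camera adjusted p 4.99e-05, and adjusted p = 0.546 with an estimated correlation), with Sdhd at -1.36. With library totals 6 fell and 2 rose. Cytosolic ribosomal protein genes rose in 17 of 36 with 0 falls, the same adjusted over the list alone (camera adjusted p 0.000182, and adjusted p = 0.546 with an estimated correlation), with Rpl3 up 1.34, and with library totals 31 rose. Of 28 cytokine and receptor genes 11 rose and 3 fell, and of 20 cell cycle genes 2 rose and 7 fell, the same adjusted over each list alone, without camera calls (adjusted p 0.324 and 0.063). Camera called the cell cycle list down in 7 alternatives, with adjusted p from 0.00318 to 0.0499, among them library totals, where 2 rose and 4 fell. Of 11 gluconeogenesis and glycogen genes 4 fell and 0 rose, the same adjusted over the list alone (camera adjusted p 0.0315, and adjusted p = 0.429 with an estimated correlation). Acute phase genes split 5 to 6 of 21, with a median of 0.25 and a camera direction of down (adjusted p 0.844), and with library totals 9 rose and 4 fell. Of 21 Wnt, Hedgehog and Notch genes 4 rose and 6 fell, and with library totals 7 rose and 3 fell.

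Markers of other cells moved apart in fibrosis against normal. Of 12 T and NK cell markers 10 fell and 0 rose (12 and 0 adjusted over the list alone; camera adjusted p 0.00173, and adjusted p = 0.445 with an estimated correlation), with Prf1 and Gzma, proteins of cytotoxic granules, at -1.62 and -2.28. With library totals only 2 of them fell. Of 6 neutrophil markers 3 rose and 1 fell (5 and 1 adjusted over the list alone), with Lcn2, which injured hepatocytes also make, up 4.47 and Retnlg at -2.84. B and plasma cell markers had 2 of 10 higher and 5 lower, cholangiocyte markers 6 of 14 higher and 1 lower, Kupffer cell and macrophage markers 1 of 19 higher and 3 lower, and sinusoidal endothelial markers 0 of 18 higher and 7 lower. With library totals the last 2 lists had 3 higher and 1 lower each. Adjusted over the list alone the counts of these 4 lists were 2 and 6, 8 and 1, 1 and 1, and 0 and 5, and camera called none of them (adjusted p 0.214, 0.103, 0.25 and 0.16), but the last 2 down without fibrosis replicate 1 (0.0266 and 0.012). Dendritic cell markers had 0 of 12 called by edgeR and 0 adjusted over the list alone. Mast cell markers had 1 of 5 higher and 3 lower, erythroid markers 2 of 7 higher and 1 lower (1 and 1, and 6 and 1, with library totals), and mesothelium and adipocyte markers 2 of 8 each way. Of 4 tested exocrine pancreas genes 3 fell, among them Cpa1, which had 0 counts in both CCl4 groups.

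In schisandrin B against fibrosis, 16 of 32 oxidative phosphorylation genes rose and 2 fell, the same adjusted over the list alone (8 and 3 with library totals; camera adjusted p 0.000448, and adjusted p = 0.75 with an estimated correlation). Ribosomal protein genes fell in 12 of 36 with 0 rises (10 and 0 adjusted over the list alone, 17 and 0 with library totals; camera adjusted p 0.0459, and adjusted p = 0.896 with an estimated correlation). Cytokine and receptor genes had 2 of 28 higher and 10 lower (2 and 8 adjusted over the list alone), and acute phase genes 1 of 21 higher and 5 lower, the same adjusted over the list alone (1 and 10 with library totals), without camera calls (adjusted p 0.177 and 0.276). In schisandrin B against normal, camera called cell cycle genes down, with 4 of 20 lower and 0 higher (9 and 0 adjusted over the list alone; adjusted p 0.0016, and adjusted p = 0.714 with an estimated correlation). It also called T and NK cell markers (4 of 12 lower, 0 higher, the same adjusted over the list alone; adjusted p 0.00735) and acute phase genes (3 of 21 lower, 0 higher, and 4 adjusted over the list alone; adjusted p 0.0368) down, each with an adjusted p = 0.714 with an estimated correlation. Camera called fatty acid oxidation (1 of 30 higher, 0 adjusted over the list alone, 8 with library totals; adjusted p 0.0156) and ribosomal proteins (1 of 36 higher, the same adjusted over the list alone, 9 with library totals; adjusted p 0.0368) up, each with an adjusted p = 0.797 with an estimated correlation.

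Splits of the 6 libraries of a comparison into 3 and 3 are too few, at 10, for a share under 0.05. As many genes as in the real split were called in 1 of 10 splits in each comparison, the real one. The real values were 7041, 6895 and 1531, and the highest of the other splits gave 0 in each.

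The libraries labelled normal held no Kdm5d or Eif2s3y counts and a female type of liver gene expression. At the rate of the other 6 libraries 1743 counts of Kdm5d, Eif2s3y and the entry Ddx3, which follows the same pattern, would be expected in them, and 2 were found, so their depth is not the cause. Hormonal feminization of male livers would leave Kdm5d and Eif2s3y on, but the upper 95% limit of their joint level in the normal libraries was 0.363% of that in the others. Female animals under the normal label stay open: 15 of 17 fixed sex-biased entries were called in the female direction in normal against schisandrin B libraries, but this restates the pattern, and Xist, which could decide, is not among the gene entries. The entry Ddx3y, which had 6 to 32 counts in every library, does not separate the groups, and other sources of the livers were not tested.

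Stress genes were high in fibrosis libraries, with 66 of 96 genes on the 4 stress lists called higher than with schisandrin B. Fibrosis replicate 1 alone does not account for them, since 63 of the 66 were called without it. A lower share of hepatocytes, with the other cells unchanged among themselves, would raise the markers of all other cells alike. These had a median of 0.11 (log2, fibrosis over schisandrin B), from -0.74 for T and NK cells to 2.56 for neutrophils. They did not rise alike. The called stress genes had a median of 2.46, but they were selected for being higher in fibrosis libraries. Over all tested members the list medians, schisandrin B against fibrosis, were -1.99 (unfolded protein), -1.66 (p53), -2.82 (heat shock) and -1.35 (Nrf2). A lower share joined by changes among the other cells cannot be told apart. Handling before freezing cannot be told apart: of 5 immediate early genes 4 (Fosb, Egr1, Ier2 and Nr4a1) were not called higher in fibrosis libraries, but these 5 left out called genes, since 4 of all 14 early response genes on the fixed list were called higher, Junb among them, while Nr4a1 was called lower, a call that 4 of 14 alternatives ended. A response to CCl4 that schisandrin B dampens, a different time since the last CCl4 dose and heat after removal stay open and were not tested.

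Col1a1, Col1a2 and Col3a1 were no higher in fibrosis than in schisandrin B libraries. The log2 values (schisandrin B over fibrosis) of Col1a1, Col1a2 and Col3a1 were 1.55 ± 0.44, 1.07 ± 0.39 and 0.72 ± 0.27. Library totals lowered them to 1.25 ± 0.49, 0.79 ± 0.43 and 0.42 ± 0.31 without a change of direction. All 3 calls ended with library totals (edgeR adjusted p 0.0574, 0.151 and 0.278). DESeq2 size factors kept them, at 1.57, 1.09 and 0.74 (edgeR adjusted p 0.0128, 0.0337 and 0.0389), so the calls depend on the choice of scaling. With library totals only Col1a1 stayed above 0 by more than 2 SE, a limit set after the values were seen. Scaling therefore does not account for the direction of Col1a1, and for Col1a2 and Col3a1 it cannot be told apart. Schisandrin B replicate 1, the highest library for all 3, is not the whole cause, since the lowest value without it was 0.65 ± 0.31, although the calls of Col1a2 and Col3a1 ended (adjusted p 0.117 and 0.114). Exchanged labels of the 2 CCl4 groups cannot be told apart from a true difference either: genes induced through PXR and CAR, a response to expect in treated livers, had a median of 1.48, but pericentral genes had a median of 2.46, so the general rise of hepatocyte genes could cover it. Collagen may also lag behind Acta2 and the stress genes, which was not tested.

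A hypothesis is that sterol and fatty acid synthesis may stay lower in CCl4-treated livers whether or not schisandrin B is given. With schisandrin B 18 of 24 cholesterol genes were called lower than in normal libraries, fry found a common direction (adjusted p 0.00179), and camera with an estimated correlation did not call the list (adjusted p = 0.201). The test leaves the hypothesis open, because it also required a call by camera with an estimated correlation. Apart from the test, the sex-linked difference of the normal libraries is confounded with CCl4.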
